A study of Homo sapiens with 8 samples.

How the data were processed

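Total RNA of HEK293 derivatives was hybridised to a human short-oligonucleotide expression array, and the values analysed were the table of 8 columns and 22283 probe sets that the submitters deposited. The deposited values are intensities on a linear scale, 1 per probe set and array, without detection calls. Every array had a 2% trimmed mean of 1000 in the table, so the columns had been brought to a common scale before deposit; the software, the background correction and the scaling step are not given in the sources used here. Array medians lay between 337.2 and 407.1. Of the probe sets, 68 were array controls and were left out of all tests. No scanner files were used here, and the number of arrays limits the precision.

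Groups were taken from the labels, which give each array a construct, a line number and an induced or noninduced state. The labels list 2 wild type lines (numbers 1 and 4), 1 C106R line (number 1) and 1 R154X line (number 6), each with 1 noninduced and 1 induced array. Induction was 1 µg/ml tetracycline for 24 h, per the labels. Nothing in the labels says that arrays of a construct came from more than 1 culture per line and state. The only replication behind a p-value is therefore between these lines, not between cultures of a line. Most of the weight in each variance comes from the limma prior described below, which is taken over all tested probe sets by intensity. A p-value here is thus not a test against the spread of that probe set between lines alone. That spread also holds the disagreement between the 2 mutant forms, which share 1 term. The 2 mutant forms are different proteins and were pooled as 1 mutant arm only so that the spread between lines could be estimated.

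The column of noninduced wild type line 1 and the column of the noninduced C106R line were identical in all 22283 probe sets. The table therefore holds 7 distinct arrays. It is not known which line that array came from, so changes of wild type line 1 may hold differences between lines as well as induction. The array was counted once and served as the noninduced array of both lines. That choice was stated before any test was run, but the fits were compared before the reported one was written out. Counting it once departs from the design set before the data were examined, which had 8 arrays and a block for each of 4 lines. The fit of that design, with the array entered for both lines, called 62 probe sets on wild type induction, 1 on mutant induction and 0 for the difference between them, and these counts stand beside the reported ones in the text. The planned test of wild type against mutant lines without induction was not made, because 2 of its 4 arrays are 1 array.

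A value of 74.1, the 20th percentile of all values, was added to each intensity before taking log2. Fold changes are on this log2(value + 74.1) scale, which understates changes of dim probe sets. Probe sets with a mean above the 30th percentile of all probe set means were kept, which left 15540 for testing. The fit used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2 residual and 15.44 prior degrees of freedom). It had a block for each of 3 sets of arrays: the shared array with the 2 induced arrays that refer to it, the pair of wild type line 4 and the pair of the R154X line. One term stood for induction in wild type lines and another for induction in mutant lines, and their difference was tested in the same fit. Calls were made at a Benjamini-Hochberg adjusted p of 0.05 over all probe sets tested. The shared array's level is estimated together with the induced C106R array. A fitted wild type change therefore also holds smaller parts of the mutant changes, the R154X change added and the C106R change subtracted. It need not lie between the changes of the 2 wild type lines.

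The line was used as a block because the labels name the line of each array and because the study is remembered to have compared induced with noninduced cells line by line; the study's own methods were not used here. Without the block, 17, 1 and 11 probe sets passed in the 3 comparisons. The fits with and without the block and with all 8 columns were looked at together before the reported one was written out.

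Probe sets were named from the array's platform annotation, with symbols checked through gene identifiers against the RefSeq annotation of GRCh38.p14, which changed 0 symbols. Of the probe sets, 19071 named 1 gene, 1043 named several and 2107 named none; only those with 1 gene are named in the text. Probe sets of the kinds designed to match several transcripts or related genes can share signal between them. No genome build goes with the table, so no coordinates are given. The level of the introduced gene is not reported here. List members with no probe set of their own name in the annotation used, or below the intensity filter, were not tested.

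Before the data were examined, 21 gene lists and 5 lists of cell type markers were fixed, along with the rule for the genes the text names. For wild type induction these were the 15 largest rises and 10 largest falls among called probe sets of 1 gene with the same direction in both wild type lines. For the difference they were the 10 largest of each direction. For mutant induction, where fewer than 10 passed, they were the 10 smallest p with the same direction in both mutant lines, as values. From each list up to 4 called members were named, or up to 2 as values where none passed. The last part of the rule also covers mutant induction and the difference, where it is printed only for the carnitine acetyltransferase gene and villin; the values of the other uncalled members are left out for length. Lists were tested with limma's camera (preset inter-gene correlation 0.01) on the probe set with the highest mean of each gene, with adjustment over 63 tests (21 lists in 3 comparisons). The same lists were run with an estimated correlation and with fry. Counts per list are also given with p adjusted over the list alone. Changes in single lines were only described, as 1 array per state has no replicate check.

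The scripts were tested on simulated data for wild type induction over 15540 probe sets. In 20 simulations with 200 changed probe sets each, 33.4% of those changed 2-fold and 78.7% of those changed 4-fold were recovered on average. Of the calls, 7.62% were false. The simulated noise was normal, independent between probe sets and of equal spread on all arrays. The measured arrays need not meet this, so these rates may not hold for the reported calls. Alternatives covered quantile normalization, centring on array medians, other pseudocounts (33.3 and 371.4), other filters, other priors, no block, separate mutant terms, fewer arrays, and each line left out. The fit of all 8 columns, the design first set, became an alternative once the identical columns were found. After the data had been seen, 2 others were added: no use of the shared array, and the noninduced R154X array as control for the lines that share theirs.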

Results

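HEK293 is an established human embryonic kidney cell line. The derivatives measured here carried a tetracycline-inducible copy of HNF4a2, a splice form of a nuclear receptor that acts as a transcription factor in liver, kidney and gut epithelium. The copy was the wild type in 2 lines, a form with a cysteine-to-arginine change (C106R) in another and a form that ends in a premature stop (R154X) in the last. Each of the 4 lines had 1 noninduced array and 1 array after 24 h with 1 µg/ml tetracycline. The comparison addresses which genes respond to HNF4a2 in kidney cells. The 2 noninduced columns of wild type line 1 and of the C106R line held identical values and were counted as 1 array, so 7 distinct arrays of 22283 probe sets entered the tests. Median intensities ran from 337.2 to 407.1. The induced arrays of wild type line 1, wild type line 4 and the R154X line had medians of 407.1, 395.5 and 402.3, and the others lay between 337.2 and 352.7.

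On induction of wild type HNF4a2, 152 of 15540 probe sets passed the threshold in the reported fit. Of these 84 rose and 68 fell, corresponding to 68 higher and 56 lower named genes. With the 8 columns as first designed 62 passed, and without the intensity trend 0. The changes of wild type line 1 may hold differences between lines as well as induction, as the origin of its noninduced array is not known. At the added value of 74.1, the highest log2 change was that of VIL1, which encodes villin, an actin-bundling protein of brush border microvilli. Its log2 change was 3.43 ± 0.67 (SE, adjusted p = 0.022), with intensities of 20.5 to 1265 in line 1 and 16.8 to 852.1 in line 4. Its noninduced intensities lay below the added value, and with the 50th percentile as pseudocount its change was 1.82, below those of CIDEB (2.02), C1orf115, DDAH2 and SELENOP. The call of VIL1 was lost in 3 of 15 alternatives, without wild type line 1 (log2 change 3.35, adjusted p = 0.223), without the shared array and without the intensity trend (0.342, the highest). CIDEB, a lipid droplet and lipoprotein protein of hepatocytes, rose by 2.84 ± 0.40 (adjusted p = 0.0032). SELENOP, the selenium transport protein of plasma, rose by 2.19 ± 0.30 (adjusted p = 0.0025), and ABCB1, the drug efflux pump P-glycoprotein, by 2.02 ± 0.32 (adjusted p = 0.0058). The kidney developmental transcription factor WT1 rose by 2.11 ± 0.37 (adjusted p = 0.013). Its changes were 1.86 and 1.97 in wild type lines 1 and 4, 1.24 in the R154X line and -0.20 in the C106R line. The 2 mutant values raised the fitted change of WT1 above those of both wild type lines.

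The other large named rises were spread over transport, metabolism and structure. The organic anion transporter gene SLCO4C1 had a log2 change of 2.46. DDAH2 had a change of 2.42, and all 3 of its tested probe sets passed. Without wild type line 1 its value was 1.58 and missed the threshold. Without the shared array it also missed the threshold (adjusted p = 0.0531), and its highest adjusted p over 17 alternatives was 0.342. ETNPPL, which encodes a phosphoethanolamine lyase, had a change of 2.23, and PRPH, which encodes the intermediate filament peripherin, a change of 2.19. ATXN7L1 (2.59), DNAJC22 (2.38), TRIM10 (2.15), C1orf115 (2.12), CALML4 (2.11) and SMAGP (1.94) completed the 15 largest. In each of these 15 genes both wild type lines moved upwards, which the naming rule required. Without wild type line 1, ATXN7L1, SLCO4C1, DNAJC22 and PRPH also missed the threshold, as did ATXN7L1 without the shared array. The other tested probe sets of TRIM10 (3), ATXN7L1 (1) and SLCO4C1 (1) did not pass.

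Among falls, the splicing factor gene PRPF31 had a log2 change of -2.66 ± 0.42 (adjusted p = 0.0058), although its other tested probe set did not pass. Its induced intensities in the wild type lines (54.3 and 39.5) lay below the added value, and with the 50th percentile as pseudocount its change was -1.35, smaller in size than those of COLEC12 and LGR5. LGR5, the R-spondin receptor that marks several epithelial stem cells, had a change of -2.08 ± 0.31 (adjusted p = 0.0039), and both of its probe sets passed. EXOSC4, a subunit of the RNA exosome, had a change of -2.16, and EHMT2, a histone H3 lysine methyltransferase, a change of -2.14. TMEM158 (-2.11), the scavenger receptor gene COLEC12 (-2.05) and NTS (-2.05), which encodes neurotensin, followed. The metallothionein gene MT1F (-1.90) fell on 1 probe set while its other probe set had the opposite sign. IFITM3 (-1.86), an interferon-inducible membrane protein gene, and the kinase gene MAPKAPK3 (-1.72) were the last of the 10. The other tested probe sets of EXOSC4 (2) and MAPKAPK3 (1) did not pass. Without wild type line 1, TMEM158, COLEC12 (-1.20), MT1F, IFITM3 and MAPKAPK3 missed the threshold, and EHMT2 did without line 4. Without the shared array these 6 and NTS missed it.

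**Figure D1:**
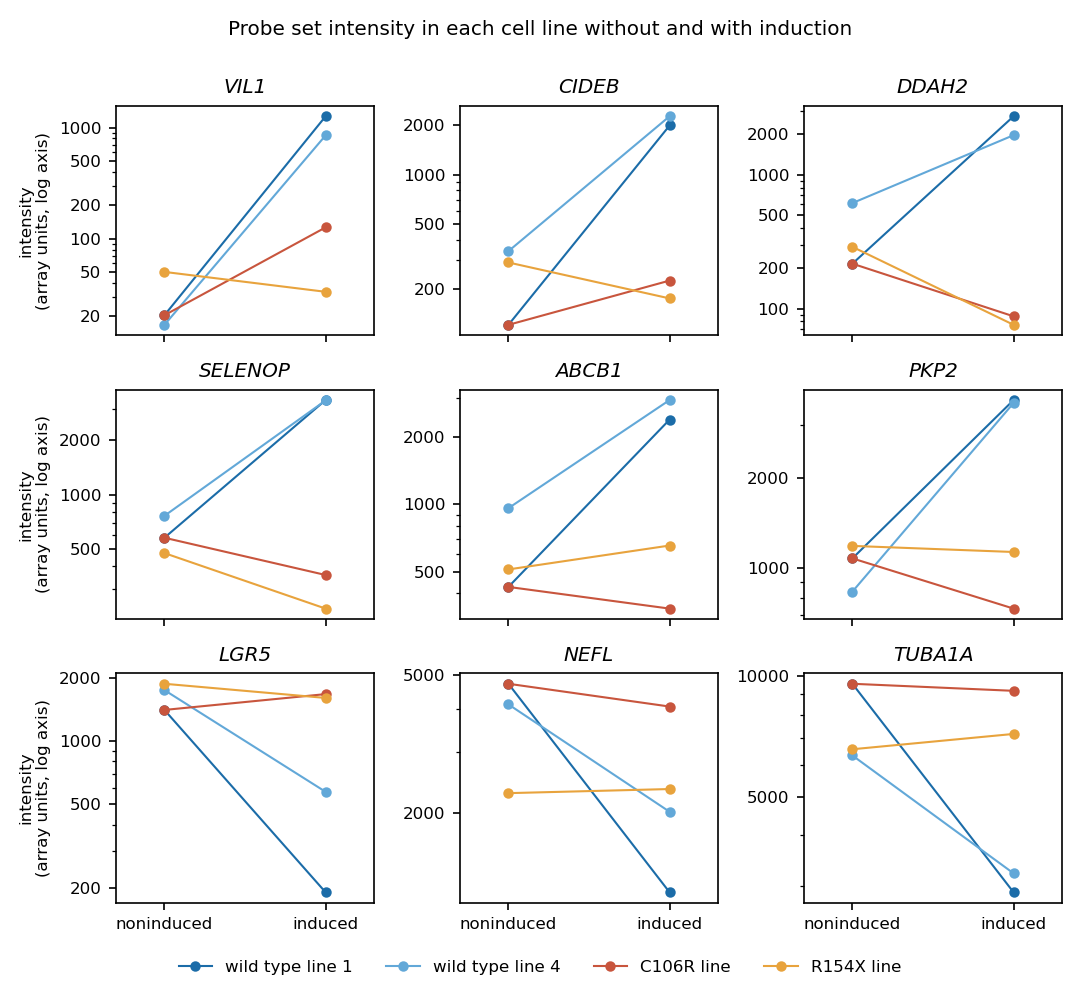
Intensity (array units, log axis) of 9 named genes in each of the 4 cell lines, noninduced and induced, 1 probe set per gene and 1 array per point; wild type line 1 and the C106R line share their noninduced point. VIL1 went from 20.5 to 1265 in wild type line 1 and from 50.3 to 33.3 in the R154X line.

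The 152 probe sets called on wild type induction changed in the same direction in both wild type lines. They were called on these same wild type arrays, so their shared direction and size there follow largely from the selection. The fitted wild type change also holds smaller parts of the mutant changes, the R154X change added and the C106R change subtracted. The selection therefore favoured the called direction in the R154X line and the opposite one in the C106R line. The median change of the 152 in the called direction was 1.51 in wild type line 1 and 1.09 in line 4. It was 0.003 in the C106R line and 0.12 in the R154X line. The called direction was found for 78 of the 152 in the C106R line and 100 in the R154X line. At least 2-fold changes in the called direction were found for 135 of them in line 1, 88 in line 4, 4 in the C106R line and 6 in the R154X line. At an unadjusted p under 0.05, limma gave 2255 probe sets where 777 would be found with no change. The number of calls depended on the fit: 62 passed with the 8 columns as first designed, 61 without the shared array, 17 without the line block, 39 without the intensity filter, 0 without the intensity trend and 1975 without wild type line 4. With arrays centred on their medians 235 passed, 52 higher and 183 lower.

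**Figure D2:**
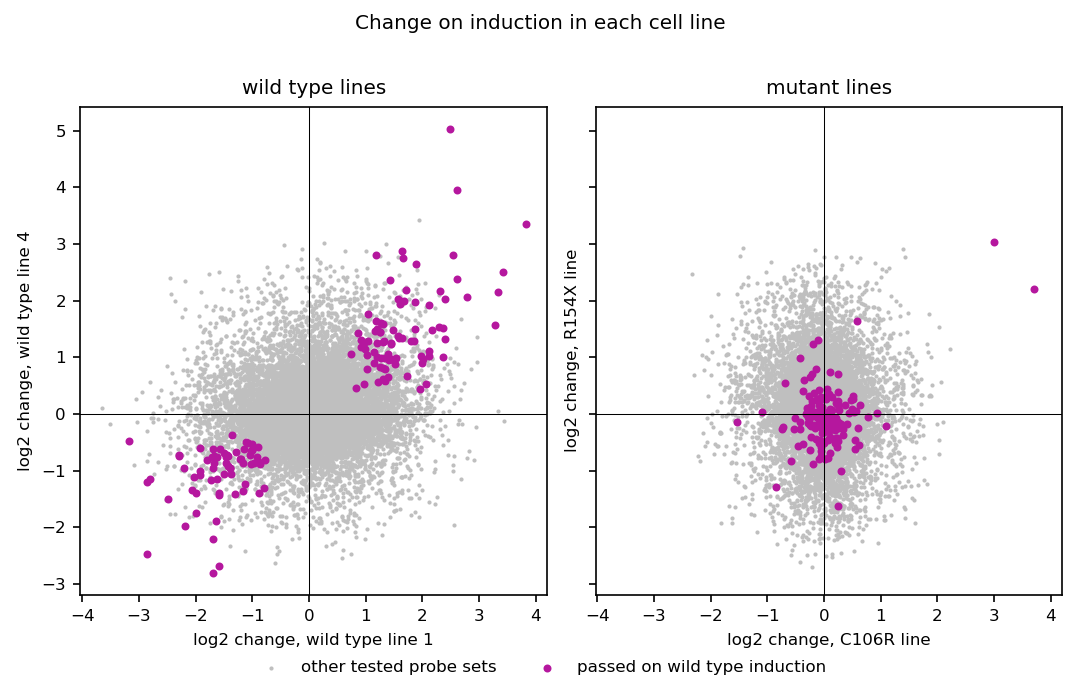
Log2 change on induction of each of the 15540 tested probe sets, wild type line 1 (x) against line 4 (y) on the left, and the C106R line (x) against the R154X line (y) on the right; darker points are the 152 probe sets that passed on wild type induction. The median change of those points in the called direction was 1.51 and 1.09 in the wild type lines, 0.003 in the C106R line and 0.12 in the R154X line. The points were selected on the fitted wild type change, which also holds smaller parts of the mutant changes.

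Genes of fatty acid oxidation and ketogenesis rose as a list on wild type induction. Of 28 tested members 3 rose and none fell (9 and 0 when adjusted over the list alone), with a median log2 change of 0.30 (camera adjusted p = 0.0015, from 0.0004 to 0.755 over 11 alternatives; adjusted p = 0.755 with an estimated correlation). The 3 were ACADVL (1.40 ± 0.24), the first enzyme of mitochondrial very long chain acyl-CoA oxidation, HADHB (1.19 ± 0.22), a subunit of the trifunctional protein, and ACAT1 (0.86 ± 0.20), the mitochondrial acetoacetyl-CoA thiolase. The call of ACAT1 (adjusted p = 0.0496) was kept in 2 of 17 alternatives, those of ACADVL and HADHB in 15 and 13, so the count of 3 rests on it. The list's median was 0.43 and 0.35 in the 2 wild type lines, -0.0047 in the C106R line and -0.19 in the R154X line.

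The oxidative phosphorylation list fell (median -0.19, 56 members, camera adjusted p = 0.00035; adjusted p = 0.755 with an estimated correlation). Its only called member was CYC1, the cytochrome c1 subunit of complex III, at -0.98 ± 0.20, also 1 when adjusted over the list alone; this call was kept in 9 of 17 alternatives. The list's median was -0.30 and -0.069 in wild type lines 1 and 4, 0.049 in the C106R line and -0.091 in the R154X line, which was lower than in wild type line 4. The mitochondrial translation list also fell (median -0.24, 47 members, camera adjusted p = 0.00035; adjusted p = 0.755 with an estimated correlation), although its only called member, the initiation factor gene MTIF2, rose by 1.27 ± 0.29. Its values were 1.95 in wild type line 1 and 0.45 in line 4, the latter being also its fitted value without line 1 (adjusted p = 0.652), and its call was lost in 10 of 17 alternatives. The list's median was -0.37 and -0.11 in wild type lines 1 and 4, 0.012 in the C106R line and -0.054 in the R154X line. Adjusted over the list alone, 1 member rose and 1 fell. Neither list passed without wild type line 1 (adjusted p = 0.489 and 0.209), and oxidative phosphorylation did not pass after quantile normalization (adjusted p = 0.309). Over all 11 alternatives the adjusted p ranged from 1.1e-05 to 0.755 and from 0.00016 to 0.755. The medians of the 2 induced wild type arrays lay above those of all noninduced arrays (395.5 and 407.1 against at most 352.7). That of the induced R154X array did too (402.3). The actin 3'/5' ratio went from 1.23 on the shared array to 1.79 in induced wild type line 1, against 1.71 and 1.74 in line 4.

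The G1/S and DNA replication list had a median of -0.21 over 36 members (camera adjusted p = 0.030; adjusted p = 0.755 with an estimated correlation). No member passed over all probe sets, and 1 rose and 2 fell when adjusted over the list alone. CHAF1B, of the chromatin assembly factor, had a log2 change of -1.05 (adjusted p = 0.078) and E2F1 one of 1.03 (adjusted p = 0.082). The list passed in only 2 of 11 alternatives, with adjusted p from 0.017 to 0.755, and did not pass without any single line (without wild type line 1, 0.209; without line 4, 0.141; without the C106R line, 0.13; without the R154X line, 0.0932). The G2/M and mitosis list was not shifted (41 members, adjusted p = 0.482) and had 0 called members, also over the list alone. AURKA had a change of -1.07, with its other probe sets of opposite sign, and CENPF one of 1.02, which came from 2.17 in wild type line 1 and -0.21 in line 4.

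**Figure D3:**
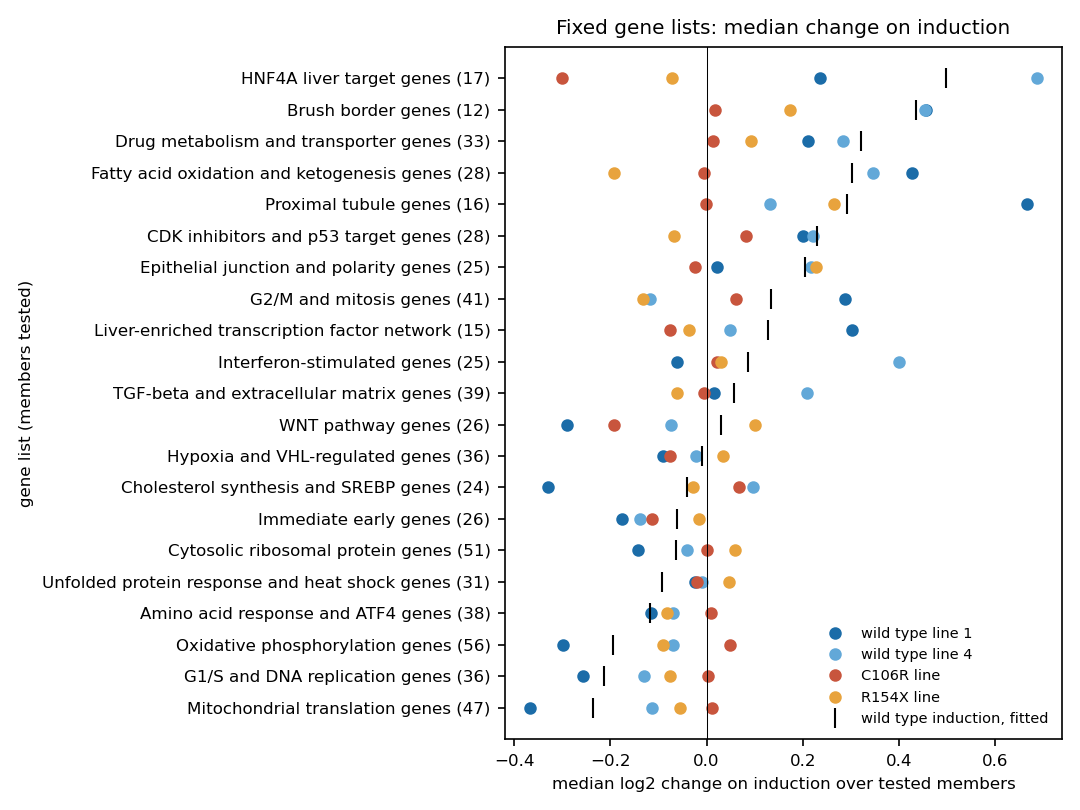
Median log2 change on induction over the tested members of each of the 21 fixed gene lists (y, number of members in brackets), in each cell line (points) and as fitted for wild type induction (bars). Fatty acid oxidation lay at 0.43 and 0.35 in the wild type lines and at -0.0047 and -0.19 in the mutant lines.

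Lists for the tissues in which HNF4a2 acts did not pass as wholes, which does not exclude a shift. Of the 61 genes of the liver target list, 51 had a probe set and 17 were above the intensity filter. These 17 had a median of 0.50 (camera adjusted p = 0.305) and 0 called members, also when adjusted over the list alone. The median was 0.24 and 0.69 in wild type lines 1 and 4, -0.30 in the C106R line and -0.071 in the R154X line. The filter on mean intensity can leave out genes that are bright in only a few arrays. APOA4, an intestinal and hepatic apolipoprotein gene, had a change of 1.52 ± 0.69 (adjusted p = 0.316) and ALB one of 1.22 ± 0.76 (adjusted p = 0.486). The liver transcription factor network (15 members, adjusted p = 0.91) had 0 called members, and 1 higher adjusted over the list alone. Its median (0.13) and mean (0.029) were positive while the test pointed down. NR2F6 stood at 0.92 ± 0.24 (adjusted p = 0.083) and CEBPB at -0.77 ± 0.30 (adjusted p = 0.238). In the proximal tubule list (16 members, adjusted p = 0.439), 0 passed over all probe sets and 1 over the list alone. The endocytic receptor gene LRP2 had a change of 1.60 ± 0.42 (adjusted p = 0.0796), and SLC34A1 one of -1.37 ± 0.68 (adjusted p = 0.366).

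In the brush border list (12 members, adjusted p = 0.149), VIL1 alone rose. In the epithelial junction list (25 members, adjusted p = 0.38), PKP2 alone rose, by 1.88 ± 0.26 (adjusted p = 0.0025); it encodes plakophilin of desmosomes, and its other tested probe set did not pass. Both counts were the same when adjusted over the list alone. Drug metabolism and transport genes (33 members, adjusted p = 0.149) included 2 rises, ABCB1 and the glutathione transferase gene MGST2 (1.04 ± 0.22, call kept in 10 of 17 alternatives and lost without the C106R line), and 3 rises and 1 fall adjusted over the list alone.

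In the cholesterol synthesis list (24 members, adjusted p = 0.482), the sterol isomerase gene EBP rose by 1.24 ± 0.21. IDI1, the isopentenyl diphosphate isomerase gene, had a change of -1.10 ± 0.20, and INSIG1, a sterol-regulated brake on SREBP processing, one of -1.16 ± 0.25, and no other tested probe set of these 3 genes passed. INSIG1 stood at -1.69 in wild type line 1 and -0.62 in line 4, and its call was kept in 11 of 17 alternatives, not without line 1 (-0.62). Adjusted over the list alone, 3 rose and 3 fell. Of the WNT pathway list (26 members, adjusted p = 0.326), LGR5 and MYC fell, and 3 fell when adjusted over the list alone; the median was 0.029 and the mean -0.23, the direction of the test. MYC, with -1.16 ± 0.23 (adjusted p = 0.022), was also the only called member of the immediate early list (26 members, adjusted p = 0.232), where 2 fell over the list alone; its call was lost without wild type line 1 (-0.86) and in 4 of 17 alternatives in all. The p53 target list (28 members, adjusted p = 0.482) had 1 rise, TP53I3 (1.76 ± 0.37), also over the list alone, with the call kept in 11 of 17 alternatives and lost without wild type line 4 (1.23). IFITM3 was the only called member of the interferon list (25 members, adjusted p = 0.866), also over the list alone. HSPD1, the mitochondrial chaperonin gene, rose by 0.67 ± 0.15 as the only called member of the unfolded protein and heat shock list (31 members, adjusted p = 0.865), in which 3 rose and 1 fell over the list alone; the call of HSPD1 was kept in 5 of 17 alternatives.

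Of 4 further lists none was shifted and none held a called member. In the hypoxia list (36 members, adjusted p = 0.38; 2 higher and 4 lower over the list alone), ENO2 had a change of -1.32 ± 0.32 (adjusted p = 0.0612), and PGK1 one of -1.71 ± 0.68 with other probe sets of both signs. The amino acid response list (38 members, adjusted p = 0.265) held SLC1A4 at -1.59 ± 0.49, where other probe sets disagreed in sign, and PSPH at -1.13 ± 0.40. The matrix and TGF-beta list (39 members, adjusted p = 0.70) held TGFB1 at 0.97 ± 0.62 and SMAD6 at 0.92 ± 0.66, the latter with a probe set of opposite sign. The cytosolic ribosomal list (51 members, adjusted p = 0.0976) held RPL14 at -0.83 ± 0.42, with a probe set of opposite sign, and RPS28 at -0.72 ± 0.34. The last 3 lists had 0 members past the threshold over the list alone.

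Markers of other cell types were not shifted on wild type induction. Camera gave adjusted p = 0.541 for neuronal markers (10 tested), 0.457 for fibroblast (8), endothelial (4) and keratin (5) markers, and 0.66 for haematopoietic markers (3). Adjusted over the list alone, 2 neuronal, 2 fibroblast and 1 keratin marker were lower and 1 endothelial marker was higher. For neuronal markers the median (0.21) and the mean (0.18) were positive while the test pointed down. The neurofilament gene NEFL was the only marker called over all probe sets, with a log2 change of -1.46 ± 0.24 (adjusted p = 0.0086). The 3'/5' intensity ratio of the actin control probe sets, a sign of RNA quality, was 1.23 on the shared noninduced array and 1.26 on the induced C106R array, against 1.71 to 2.21 on the other 5.

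On induction of the mutant forms, tested as 1 arm, 2 probe sets passed, both upwards in both mutant lines. Neither has a gene name in the annotation used, and both also rose on wild type induction. At an unadjusted p under 0.05, limma gave 255 probe sets, fewer than the 777 found with no change. With the 8 columns as first designed 1 passed, and no intensity trend left 0. Without wild type line 1, 9 passed, without wild type line 4, 6, and without the C106R line, 1. None of the 21 lists was shifted (smallest adjusted p = 0.197, fatty acid oxidation, median -0.08).

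The 10 named genes with the smallest p on mutant induction all had an adjusted p of 0.9997. The negative values were -1.33 ± 0.32 for MIIP, -1.64 ± 0.40 for HLA-DQB1, -1.41 ± 0.35 for RAP1GAP2, -1.42 ± 0.40 for C6orf47, -1.90 ± 0.54 for CIC, -1.47 ± 0.45 for FN1 and -1.36 ± 0.42 for SMOX. The positive ones were 2.26 ± 0.66 for CTSZ, 1.13 ± 0.35 for SMAGP and 0.76 ± 0.24 for TAF15. MIIP and HLA-DQB1 had other probe sets of opposite sign.

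An effect of tetracycline alone would cancel in the difference between wild type and mutant induction. Baseline differences between wild type line 1 and the C106R line would not, as their induced arrays are set directly against each other. Unequal RNA quality of these arrays would not cancel either. Their actin 3'/5' ratios were 1.79 for wild type line 1 and 1.26 for the C106R line. The difference passed for 23 probe sets, which named 20 genes, 17 in favour of wild type and 6 the other way. Of these, 22 also passed on wild type induction. DDAH2 differed by 3.70 ± 0.50 (SE, log2, adjusted p = 0.0050). Its log2 changes were 3.27 and 1.58 in the wild type lines and -0.85 and -1.28 in the mutant lines. The fitted difference gives wild type line 1 and the C106R line more weight, so it is not a plain difference of averages. SELENOP differed by 2.94 ± 0.36 (adjusted p = 0.0031), CIDEB by 2.88 ± 0.48 (adjusted p = 0.018) and PKP2 by 2.14 ± 0.31 (adjusted p = 0.0064). SLCO4C1 (2.67), MIIP (2.40), CALML4 (2.21), ABCB1 (2.12), MAN1A1 (1.88), a mannosidase gene of N-glycan trimming, and C1orf115 (1.83) were the other large positive differences. The other tested probe sets of SLCO4C1, MIIP, CALML4, PKP2 and MAN1A1 did not pass this test.

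The 6 negative differences were in PRPF31 (-2.59 ± 0.50), LGR5 (-2.24 ± 0.37), BASP1 (-1.67 ± 0.30), NEFL (-1.49 ± 0.29), PNMA2 (-1.47 ± 0.28) and TUBA1A (-1.46 ± 0.24). BASP1, NEFL, PNMA2 and TUBA1A are abundant in neurons. The calls of PRPF31 and NEFL were kept in 5 of 17 alternatives and that of PNMA2 in 4, and no other tested probe set of PRPF31, LGR5, NEFL or PNMA2 passed this test. Without wild type line 1, ABCB1, CIDEB, DDAH2, SLCO4C1, BASP1 (-0.83), NEFL (-0.91), PNMA2 and PRPF31 missed the threshold. Without the C106R line only SELENOP, CIDEB, DDAH2, MIIP and CALML4 passed among those named, with C1orf115 at 0.97; without the R154X line NEFL, PNMA2 and PRPF31 missed it. For LGR5 the mutant lines changed by 0.24 and -0.21, against -2.49 and -1.49 in the wild type lines. VIL1 did not pass this test (difference 3.01 ± 0.80, adjusted p = 0.143); it stood at 1.08 in the C106R line and -0.21 in the R154X line.

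The number of calls for the difference depended on the fit. The reported limma fit gave 1761 probe sets at an unadjusted p under 0.05, where 777 would be found with no change. With the 8 columns as first designed, limma called 0 probe sets, with 747 at an unadjusted p under 0.05, no more than with no change. All 23 kept their direction there with an unadjusted p under 0.05, at a median size of 2.002 against 2.143. Without the shared array 73 passed, and all 23 were among them. That array cancels in the fitted difference, so the estimates were the same (median size 2.143) and only the spread differed. This fit therefore says nothing on the doubt about the array. The counts were 6 without the C106R line, 48 without the R154X line, 74 without wild type line 1 and 1806 without line 4; no block gave 11, no filter 5, quantile normalization 11 and no intensity trend 0. After centring on medians 36 passed, 17 higher and 19 lower.

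In all, 4 lists differed between wild type and mutant induction by camera. Fatty acid oxidation was higher with wild type (median difference 0.50, adjusted p = 0.00015), with 0 members called over all probe sets and 6 higher over the list alone. CRAT, the carnitine acetyltransferase gene, differed by 2.46 ± 0.57 (adjusted p = 0.0977). Oxidative phosphorylation (median -0.22, adjusted p = 0.00050), mitochondrial translation (-0.28, 0.0047) and cytosolic ribosomal genes (-0.11, 0.019) were lower, with 0 called members each, also over the list alone. The ribosomal median lay at percentile 37.9 of random lists matched on mean expression, whose own median was -0.097. With an estimated correlation all 4 had an adjusted p = 0.755. The 3 lower lists lost their call without wild type line 1 (adjusted p = 0.632, 0.569 and 0.296) or without the C106R line (0.756, 0.387 and 0.161). Over the 11 alternatives they ranged from 1.1e-05 to 0.756, from 0.0016 to 0.755 and from 0.00064 to 0.755.

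Within single lines, which have no replicate check, at least 2-fold changes were counted. They numbered 2903 probe sets in wild type line 1, 1738 in wild type line 4, 725 in the C106R line and 1817 in the R154X line. The count of wild type line 1 uses the shared array, which may be the C106R line's own. That count may therefore hold differences between lines as well as induction. Noninduced arrays of different lines differed at least 2-fold in 1428 to 1982 probe sets. In both wild type lines 262 were higher and 115 lower, where independent lists would share 117.8 and 49.4. In both mutant lines 46 were higher and 34 lower, where independent lists would share 19.7 and 20.9. Opposite changes in the 2 wild type lines numbered 76 and 109, with 59.3 and 98.2 for independent lists. Of the shared wild type changes, 182 rises and 99 falls were in neither mutant line. Rises of at least 2-fold numbered 283 in the C106R line and 1083 in the R154X line, and falls 442 and 734. Independent lists would thus leave most of the 262 and 115 in neither mutant line. The 182 and 99 therefore do not show changes particular to wild type. The correlation of changes across probe sets, which are not independent replicates, was 0.147 between the wild type lines (Spearman 0.14). It was 0.297 between wild type line 1 and the C106R line (Spearman 0.276), which share the noninduced array. Simulation with no effect gave 0.501 (covariance 0.104 observed, 0.181 simulated), but with the same spread for all arrays, which fixes that value. The changes themselves had an SD of 0.783 and 0.45. The lower observed value therefore does not show less agreement than with no effect. The other 4 pairs lay between -0.07 and 0.11.

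In the C106R line MAP2K5 (2.22), ICA1 (2.10) and ZNF174 (2.06) had the highest single-line values, from noninduced intensities of 20.5, 21.0 and 16.3, and RGSL1 (-2.33), FUT2 (-2.29) and C6orf47 (-2.23) the lowest. In the R154X line they were MIER2 (2.93), EDAR (2.89) and SUGP1 (2.79), and ELF4 (-2.70), FLT4 (-2.53) and SH3GLB2 (-2.51). Most of these values, and so their order, depend on the added value of 74.1: in the C106R line RGSL1 ended at 26.1 and FUT2 at 22.9, and in the R154X line MIER2 started at 13.7 and EDAR at 52.2, while ELF4, FLT4 and SH3GLB2 ended at 35.5, 45.4 and 20.9.

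Without induction there were 3 distinct arrays, compared without a test. The shared array differed at least 2-fold from that of wild type line 4 in 1982 probe sets and from that of the R154X line in 1820, and the latter pair differed in 1428.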

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

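The matched random lists, and the use of quantile normalization and of the fit without wild type line 1 to weigh explanations, were tests chosen after the results had been seen; the test of the difference, the list tests, these alternative settings themselves and the comparison with other splits were planned. In the fitted difference the induced arrays of wild type line 1 and the C106R line are set directly against each other. Differences between these lines before induction therefore stay in it. Unequal RNA quality of these 2 arrays would stay as well (actin 3'/5' ratio 1.79 for wild type line 1 and 1.26 for the C106R line). The design first set, with all 8 columns, called 0 probe sets for the difference, and so did the fit without the intensity trend. With these limits, the test of the difference itself called 23 probe sets whose change on induction differed between wild type and mutant lines. Among its 20 named genes, the 10 with the largest higher values were DDAH2 (wild type minus mutant log2 change 3.70), SELENOP (2.94), CIDEB (2.88), SLCO4C1 (2.67), MIIP (2.40), CALML4 (2.21), PKP2 (2.14), ABCB1 (2.12), MAN1A1 (1.88) and C1orf115 (1.83), and the 6 lower ones were PRPF31 (-2.59), LGR5 (-2.24), BASP1 (-1.67), NEFL (-1.49), PNMA2 (-1.47) and TUBA1A (-1.46). By camera on the same difference, 4 gene lists differed: fatty acid oxidation (median 0.50), oxidative phosphorylation (-0.22), mitochondrial translation (-0.28) and cytosolic ribosomal genes (-0.11). All 4 had an adjusted p = 0.755 with an estimated correlation. The ribosomal median lay at percentile 37.9 of random lists matched on mean expression, whose own median was -0.097, so it was not low for genes that bright.

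A 4-line design has 3 splits into 2 arms of 2 lines, too few for a share under 0.05. The real split called 152 probe sets in the wild type arm, and the highest count in an arm of the other splits was 2; only 1 split, the real one, reached 152.

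One pattern concerns the metabolic lists, where fatty acid oxidation rose on wild type induction while oxidative phosphorylation and mitochondrial translation fell, each only with the preset correlation (adjusted p = 0.755 with an estimated correlation). Differing intensity distributions of the arrays are argued against for fatty acid oxidation (adjusted p = 0.0016 after quantile normalization, median at percentile 99.5 of 10000 random lists matched on mean expression) and as the whole cause for mitochondrial translation (adjusted p = 0.0176 after quantile normalization, percentile 0.39). For oxidative phosphorylation they remain open, since its call ended after quantile normalization (adjusted p = 0.309) while its median lay at percentile 3.73. Wild type line 1 alone may carry both falls, as the lower adjusted p without it was 0.209 and the actin 3'/5' ratio, a sign of RNA quality, went from 1.23 to 1.79 in that line against 1.71 to 1.74 in line 4, but not the rise in fatty acid oxidation, which had a median of 0.35 in line 4 and an adjusted p of 0.000404 without line 1, if line 4 is assumed to vary like the other groups. That fatty acid oxidation answers to functional HNF4a2 and not to the mutant forms stays a hypothesis: the lists differed (adjusted p = 0.00015), but not with an estimated correlation (adjusted p = 0.755).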

How the results depend on the processing

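The fit without the shared array and the use of the R154X noninduced array as a control for 2 lines were chosen after seeing the data. The fit with all 8 columns is the design first set, and it became an alternative after the identical columns were seen. Every one of the 152 calls on wild type induction and the 23 calls of the difference kept its direction in each alternative fit in which it was tested; these fits share arrays, so this is not independent evidence. Of the 152, 146 had an unadjusted p under 0.05 without wild type line 1, and 69 passed there among 186. Leaving out a line leaves its arm with 1 line, which is assumed to vary like the other groups (1 residual degree of freedom). The cause was not tested for the changes below, except that leaving out arrays leaves fewer residual degrees of freedom.

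On wild type induction 152 became 235 with arrays centred on their medians (52 higher, 183 lower; the median of all probe sets moved from 0.05 to -0.15), 39 with no filter, 0 with no intensity trend in eBayes (1758 at an unadjusted p under 0.05), 62 with all 8 columns and 61 without the shared array. Leaving out a line gave 141 to 1975, the highest without wild type line 4. On mutant induction 2 became 1 with quantile normalization, no filter, robust eBayes and all 8 columns, 0 with no intensity trend, and 1 to 9 with a line left out. For the difference 23 became 11 with quantile normalization, 36 with median centring (17 higher, 19 lower), 15 with the 10th percentile as pseudocount, 5 with no filter, 12 with the filter at the 50th percentile, 0 with no intensity trend (1375 at an unadjusted p under 0.05), 15 with robust eBayes, 49 with separate mutant terms, 37 with induced arrays only, 0 with all 8 columns and 73 without the shared array; leaving out a line gave 6 to 1806 (6 without the C106R line, 1806 without wild type line 4). Quantile normalization, other pseudocounts, the filter at the 50th percentile, robust eBayes, separate mutant terms and wild type lines only left wild type induction within 1.5 times (118 to 168).

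Cell lines pair the arrays, so the line was the block, except that wild type line 1 and the C106R line formed 1 block through their shared array. With no replicate block, 17 passed on wild type induction, all among the 152, 1 on mutant induction and 11 for the difference. The planned use of all noninduced arrays as 1 control group is that same fit once the shared array is counted once. Without the block, lists shifted numbered 4, 1 and 3.

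Lists shifted numbered 4 on wild type induction, 0 on mutant induction and 4 for the difference. These became 0, 0 and 0 with an estimated correlation and with fry. Quantile normalization gave 2 on wild type induction and 1 on mutant induction (cytosolic ribosomal genes, adjusted p = 0.0309), and without the shared array mutant induction had 1 (G2/M, adjusted p = 0.0048). Leaving out a line gave 1 to 3, 0 to 1 and 1 to 5.

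The 281 probe sets changed in both wild type lines and neither mutant line became 882 at 1.5-fold, 52 at 3-fold, 450 with no filter, 129 with the filter at the 50th percentile and 49 with the 50th percentile as pseudocount. After quantile normalization they were 284, of which 130 were higher, against 182 of the 281. The correlation between the wild type lines was 0.147, and 0.0959 with no filter; it was 0.199 with the R154X noninduced array as control for line 1.

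The planned comparison of the lines without induction and its alternatives were not run, because 2 of its 4 arrays hold the same values. Among values of single named genes under the alternatives, 1067 kept their direction and side of the threshold, 277 lost the call, 13 gained it and 2 moved. Dim probe sets limit the folds: VIL1 started at 20.5 and 16.8, below the added value of 74.1, and no detection calls were used here.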

Other observations

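Apart from the lists and the counts of calls, the genes and tests in this part were chosen after their values had been seen. The genes below were picked singly from those called on wild type induction; no list or enrichment test stands behind them as groups. SEC23A, a coat component of vesicles leaving the endoplasmic reticulum, rose by 1.75 ± 0.22 (log2, SE, limma adjusted p = 0.0017), and both of its called probe sets rose. The mannosidase gene MAN1A1 rose by 1.42 ± 0.23, the nucleotide sugar transporter gene SLC35D1 by 1.38 ± 0.29 and UGDH, which makes UDP-glucuronate, by 1.28 ± 0.27. MCFD2, a cofactor of cargo export from the endoplasmic reticulum, had a change of -1.42 ± 0.30. MAN1A1, SLC35D1 and MCFD2 each had other tested probe sets that did not pass. CFLAR rose by 1.84 ± 0.29 on 1 probe set, while its other probe sets did not pass, BIRC2 by 1.79 ± 0.26 and AIFM1 by 1.08 ± 0.20. The thioredoxin reductase gene TXNRD1, a selenoprotein gene like SELENOP, rose by 1.03 ± 0.19, and SELENBP1, which encodes a selenium-binding protein, by 1.80 ± 0.38.

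Of the 56 lower genes, 5 more are given singly. JAG1, a Notch ligand gene, had a log2 change of -1.27 ± 0.27, GAS1 of -1.22 ± 0.26, FOXF2 of -1.16 ± 0.26, and the imprinted gene PEG10 of -1.08 ± 0.23 on the more changed of its called probe sets. IRS2, the insulin receptor substrate gene, had a change of -1.28 ± 0.26; JAG1 and IRS2 had other probe sets that did not pass. All passed at an adjusted p under 0.05 by limma, and none of these 5 passed the test against mutant induction.

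NEFL, BASP1, TUBA1A and PNMA2, genes abundant in neurons, fell on wild type induction. A candidate explanation was a fall of neuronal gene expression of the line as a whole. The neuronal markers fixed beforehand do not decide this: their median log2 change was 0.21 over 10 members. The standard error of their mean, 0.28, treats genes as replicates. Among members that did not pass, DCX (1.44 ± 0.58) and SYT1 (1.11 ± 0.70) had positive values, while UCHL1 (-0.63 ± 0.18), TUBB3 (-0.37 ± 0.23) and INA (-0.10 ± 0.27) had negative values, and the list test pointed down. NEFL, UCHL1, TUBB3 and INA had the smallest standard errors and were negative, while the positive values had larger ones. A fall of all or part of the neuronal genes stays open, and PRPH, an intermediate filament gene of peripheral neurons outside that list, rose.

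The identical noninduced columns of wild type line 1 and the C106R line are a pattern with more than 1 possible explanation. The array may be the C106R line's own: the SD of its log2 difference to the induced C106R array was 0.45, against 0.583 to 0.783 for the other pairs of arrays and 0.783 to the induced array of wild type line 1. The 2 arrays may also have been processed together, apart from the other 5: their actin 3'/5' ratios were 1.23 and 1.26, below the range of 1.71 to 2.21. The first and the second explanation do not exclude each other, and no biological explanation was tested. If the array belonged to the C106R line, the change of wild type line 1 would hold differences between lines as well as induction.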
